A study of Caenorhabditis elegans with 4 samples.

How the data were processed

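RNA of Caenorhabditis elegans was compared on 4 two-channel arrays. Per the labels, channel 2 of each array held total RNA of 1 of 4 separate preps of glp-4 animals at the L4 stage, the last larval stage, and channel 1 held a wild-type mixed-stage reference. The labels name no allele, growth temperature or staging method, and no other group of samples was analysed here.

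The deposited values are log2 ratios between the channels of each array. The log base was read from the values: 2 raised to the value was a whole number of thousandths (within 0.01 of a thousandth) for 100% of the values with a ratio under 20 on each array, against at most 3.63% for the inverse ratio, 2.59% for base e and 2.58% for base 10. The direction is not stated by the labels. The ratio stored in thousandths shows only that the values were not inverted after storage, and cannot tell which channel was divided by the other. The direction was read as glp-4 L4 over reference, which is likely from the order of the channels alone. Every higher or lower in the text rests on this reading. The negative ratios of the germline, oocyte and sperm lists go the same way, but those lists were chosen for the name glp-4, so their sign is circular as support. The scanner, background correction, dye normalization, centring and spot filter are not given in the sources used here. The column medians were 0.02, -0.03, -0.12 and -0.08 for preps 1 to 4, with SDs of 0.92, 0.99, 1.06 and 1.09. Intensities were not used here, so the dimness of a spot and the compression of large ratios could not be judged, and the number of arrays limits the precision.

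The table held 21632 probes, of which 20845 had a value on all 4 arrays, 651 on 3 and 136 on 2 or fewer. Values were missing for 300, 435, 180 and 144 probes on preps 1 to 4. Names came from the platform annotation, which can be old, updated to a RefSeq gene table of assembly WBcel235 through gene ID (16360 probes), transcript accession (8 probes) or symbol and locus tag (82 probes). In all, 16450 probes had 1 gene symbol, 247 had several and 4935 had none here. Probes with several or none were kept under their own number. Probes of a gene were averaged on each array, giving 14943 named genes. Of these, 1456 had more than 1 probe, with a median range of 0.22 between probe means. For 27 genes the probes lay on opposite sides of 0, each by at least 0.5. Probes of near-identical gene copies, such as the msp, histone, pud and some collagen genes, can bind each other's transcripts, so single members of those families are uncertain.

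Items (named genes and unnamed probes) with values on at least 3 arrays entered the test, 19989 in all, of which 14940 were named genes. The mean log2 ratio was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit with an intercept, eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05), and against a 2-fold change with limma's treat. The reference was the only counterpart, so its own spread is left out of every test. Gene lists fixed beforehand were tested with limma's camera on items measured on all 4 arrays, with a preset inter-gene correlation of 0.01 and adjustment over 21 lists. Camera was also run with an estimated correlation, where its test has 3 degrees of freedom. The X chromosome was compared with the autosomes by an exact sign-flip permutation test over preps and by Fisher's exact test over genes, which are not independent replicates. Replicate error is given as the SD over the 4 preps. The named genes were glp-4, then the 6 largest positive and the 6 largest negative mean log2 ratios among named genes past the threshold, measured on all 4 arrays with 1 sign, then the 2 members of each list with the largest absolute mean among those that met the same conditions. Other genes named in the text were chosen after their values were seen.

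The alternatives set before the data were examined were: arrays centred on their medians, arrays centred and scaled alike, items on all 4 or on at least 2 arrays, each prep left out, the code shared by the titles of preps 3 and 4 as a random block, those preps averaged, a fit per probe, robust and no moderation, an absolute mean log2 ratio of at least 1, an adjusted p under 0.01, camera with ranks, every sign turned, and the X comparison without the germline, oocyte, sperm and mitosis lists. limma's duplicateCorrelation returned no value for 4 arrays in 3 blocks, so the block's correlation, 0.34, was taken from the variance within and between blocks and passed to lmFit. The steps were tested on simulated data for this comparison: 19989 items with the real spread per item on 4 arrays, of which 200 were changed. Of items changed by 0.5, 1 and 2 on the log2 scale, 8.96%, 92.5% and 100% were recovered. Of the calls, 8.22% (12 of 146) were unchanged items, against a nominal 5%. Only 200 items were changed there, while 44.96% of the real items were called. A p-value therefore had to be smaller to pass in the simulation, and these shares do not give the recovery or error rate in the real data. Of 200 random lists, 1% had a camera p under 0.05, and a list of 40 shifted by 1 had a camera p of 0.00016 with an estimated correlation. The simulated items were independent of each other, while the estimated correlation of the real lists reached 0.88 (vitellogenins). The simulation therefore does not test camera on lists whose genes vary together. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for tables, permutations and plots.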

Results

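Transcript levels were measured in 4 preps of glp-4 L4 larvae, each set against a wild-type mixed-stage reference on its own array. The gene glp-4 encodes a valyl-tRNA synthetase, and mutants of it are known for a germline that fails to proliferate at the restrictive temperature. The reference is mixed in stage and carries a germline, so a ratio holds the difference in genotype and the difference in stage together, and these arrays do not separate them. Higher and lower mean glp-4 L4 over reference, the likely direction of the deposited ratio. Labels call the samples separate preps without saying how they were grown, so the p-values measure the spread between these preps.

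The probe annotated to glp-4 also lists agef-1, so glp-4 had no level of its own. That probe had a mean log2 ratio of 1.20 ± 0.55 (SD, n = 4; limma adjusted p = 0.0019), which checks nothing about glp-4 itself.

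Among the 6 largest positive ratios of named genes were 2 cuticle collagens, and among the 6 largest negative ones were several genes known from oocytes. The infection response gene irg-5 had a mean log2 ratio of 6.32 ± 0.20 (SD, n = 4). It was followed by dod-21, a gene known as a target downstream of DAF-16, at 5.89 ± 1.305, the cuticle collagen bli-2 at 5.78 ± 0.57, pud-4 at 5.68 ± 0.49, the collagen col-120 at 5.47 ± 0.19 and pud-2.1 at 5.37 ± 0.23. The largest negative ratios of named genes were those of pos-1, a maternal RNA-binding protein, at -5.06 ± 0.67, mesp-1, a protein of the meiotic spindle, at -5.06 ± 0.24, the lectin gene clec-87 at -5.04 ± 0.22, egg-1, an egg surface receptor needed for fertilization, at -5.03 ± 0.24, oma-2, which acts in oocyte maturation, at -4.91 ± 0.39, and the Y-box gene cey-3 at -4.90 ± 0.06. The limma adjusted p of these 12 genes was at most 1.7e-05, and each had 1 sign in 4 of 4 preps.

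Over all items, 8987 of 19989 (44.96%) had a ratio different from 0, 4113 higher and 4874 lower (limma, adjusted p under 0.05), of which 3497 and 3602 were named genes. Past a 2-fold change lay 1718 items, 876 higher and 842 lower (limma treat). The median SD between preps was 0.30, and 93.5% of the items different from 0 had values on all 4 arrays with 1 sign. Pearson's r between preps, across items that are not independent replicates, ran from 0.74 (preps 1 and 3) to 0.90 (preps 3 and 4). Without moderation of the variances the first count was 5305, and 3980 of the items had an absolute mean log2 ratio of at least 1.

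**Figure D1:**
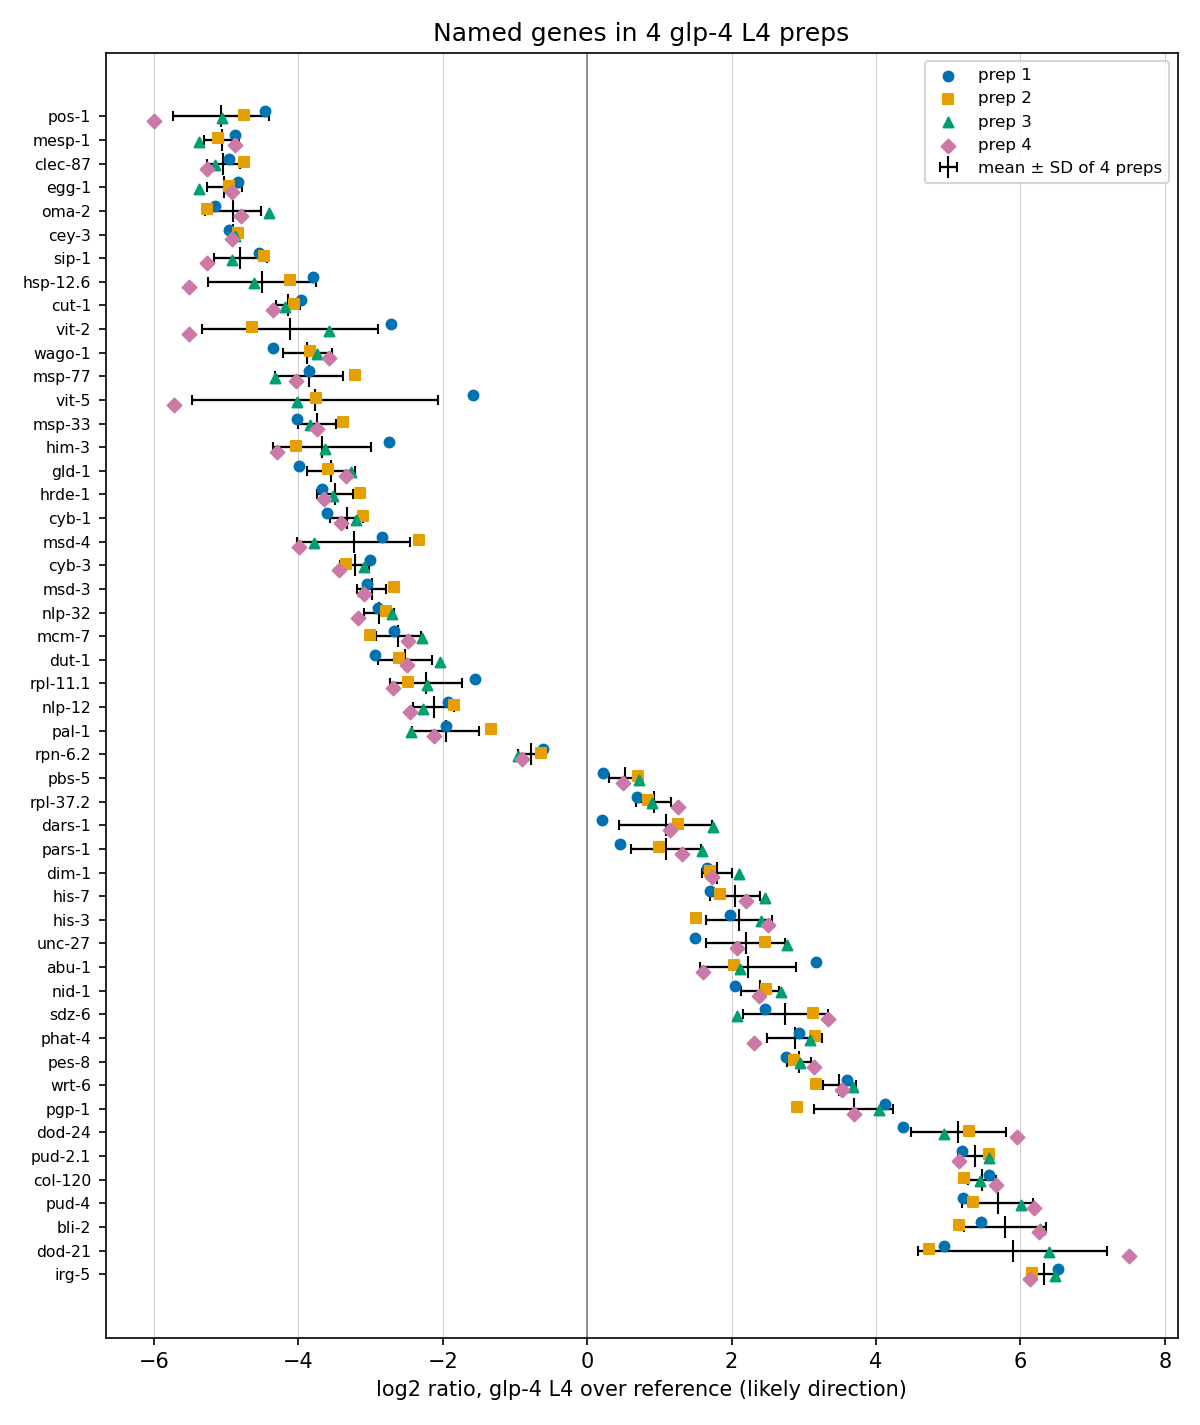
Log2 ratio of glp-4 L4 over reference (likely direction, x axis) for each named gene (y axis) in 4 preps, with coloured points for preps and black bars for the mean ± SD. The means run from -5.06 for pos-1 to 6.32 for irg-5, and vit-5 is among the widest, from -5.72 on prep 4 to -1.58 on prep 1.

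Germline genes were lower as a group. Of 43 measured genes of meiosis and germline stem cells, 39 were lower and 0 higher (41 lower adjusted over the list alone), with a list median of -1.81 ± 0.13 (SD over 4 preps). The chromosome axis gene him-3 had -3.68 ± 0.68 and the translational repressor gld-1 -3.55 ± 0.33. Of 31 genes of P granules and small RNA pathways, 26 were lower and 0 higher (27 lower adjusted over the list alone), with a median of -1.78 ± 0.12, led by the Argonaute genes wago-1 at -3.87 ± 0.34 and hrde-1 at -3.50 ± 0.25. Of 46 oocyte and maternal genes, 42 were lower and 0 higher (43 lower adjusted over the list alone), and the median was -3.26 ± 0.10. By camera, these lists had an adjusted p of 5.7e-17, 3.6e-13 and 5.5e-21 in this order. These calls were lost with an estimated correlation, with adjusted p = 0.12, adjusted p = 0.12 and adjusted p = 0.078 with an estimated correlation.

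Sperm genes were lower too. All 30 measured major sperm protein genes, which encode the cytoskeletal protein of nematode sperm, were lower (30 adjusted over the list alone), with a median of -3.08 ± 0.17, and among them msp-77 had -3.86 ± 0.47 and msp-33 -3.74 ± 0.27. Of 42 other sperm genes, 23 were lower and 2 higher (23 and 2 adjusted over the list alone), with a median of -0.58 ± 0.13, and among those measured on all 4 arrays msd-4 at -3.23 ± 0.78 and msd-3 at -2.98 ± 0.20 had the most negative means. On 3 arrays msd-1, named after its value was seen, had -3.16 ± 0.55. The 2 higher ones, named after their values were seen, were spe-4 at 1.103 ± 0.57 and swm-1 at 0.53 ± 0.33, and without prep 2 or prep 4 only 1 was called. For the msp list the camera adjusted p was 1.3e-20 (adjusted p = 0.12 with an estimated correlation) and for the other sperm genes it was 1.6e-05 (adjusted p = 0.12 with an estimated correlation). Near-identical msp copies can bind each other's probes, which leaves the values of single msp genes uncertain.

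The vitellogenins, yolk proteins made in the adult intestine, were lower with a wide spread. The 3 measured genes, vit-2 at -4.11 ± 1.22, vit-5 at -3.77 ± 1.70 and vit-6 at -3.55 ± 1.70, all passed, also adjusted over the list alone (3 lower). Their median was -1.58, -3.76, -4.01 and -5.51 on preps 1 to 4. The camera adjusted p was 0.013, and adjusted p = 0.37 with an estimated correlation. Without moderation only 1 of the 3 passed.

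Genes of cell division were lower. Of 35 DNA replication genes, 30 were lower and 0 higher (31 lower adjusted over the list alone), with a median of -1.39 ± 0.09, including the helicase subunit mcm-7 at -2.61 ± 0.31 and the dUTPase dut-1 at -2.52 ± 0.37. Of 43 genes of mitosis and chromosome segregation, 36 were lower and 0 higher (36 lower adjusted over the list alone), with a median of -1.15 ± 0.22, and the B-type cyclins cyb-1 and cyb-3 had -3.33 ± 0.22 and -3.22 ± 0.20. Camera gave an adjusted p of 2.7e-12 for replication (adjusted p = 0.15 with an estimated correlation) and 3.1e-13 for mitosis (adjusted p = 0.21 with an estimated correlation). Histone genes went the other way: 28 of 55 were higher and 8 lower (29 and 8 adjusted over the list alone), with a median of 0.47 ± 0.23 and a camera adjusted p of 6.4e-05 (adjusted p = 0.42 with an estimated correlation). The H2A genes his-3 and his-7 had 2.1004 ± 0.45 and 2.05 ± 0.35. The lower side counted 3 without prep 2 and 4 without prep 4, and near-identical copies make single histone genes uncertain.

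Epidermal genes were mostly higher, on both sides of wide ranges. Of 151 cuticle collagens, 89 were higher and 22 lower (91 and 23 adjusted over the list alone), with a median of 1.01 ± 0.35, and bli-2 and col-120, above, led them. Of 51 genes of moulting and epidermis, 34 were higher and 4 lower (34 and 4 adjusted over the list alone), with a median of 1.01 ± 0.20. The hedgehog-related gene wrt-6 had 3.49 ± 0.22, and cut-1, a cuticlin known from the dauer larva, had -4.14 ± 0.17. The other lower ones, named after their values were seen, were cut-6 at -1.09 ± 0.10, let-413 at -0.93 ± 0.63 and nhr-25 at -0.38 ± 0.10, and 7 were lower without prep 1. Collagens had a camera adjusted p of 8.2e-10 (adjusted p = 0.18 with an estimated correlation) and 2.0e-08 for moulting and epidermis (adjusted p = 0.12 with an estimated correlation).

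Intestinal genes other than vitellogenins were higher. Of 59, 41 were higher and 7 lower (42 and 7 adjusted over the list alone), with a median of 1.33 ± 0.10. The largest were dod-24, another gene downstream of DAF-16, at 5.14 ± 0.66 and the transporter pgp-1 at 3.69 ± 0.55. For this list the camera adjusted p was 1.9e-10, and adjusted p = 0.12 with an estimated correlation.

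More muscle genes were higher than lower. Of 50, 21 were higher and 4 lower (21 and 5 adjusted over the list alone), with a median of 0.41 ± 0.17, and troponin I unc-27 had 2.196 ± 0.55 and dim-1 1.80 ± 0.20. The 4 lower ones, named after their values were seen, were sca-1 at -1.20 ± 0.52, myo-2 at -1.03 ± 0.38, tni-4 at -0.65 ± 0.28 and myo-5 at -0.57 ± 0.40; myo-2 and tni-4 are pharyngeal genes, and 2 were lower without prep 4. The camera adjusted p was 0.00035 for muscle (adjusted p = 0.40 with an estimated correlation), and without moderation 11 were higher and 2 lower.

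Neuronal genes were lower by a small amount. Of 157, 84 were lower and 6 higher (87 and 8 adjusted over the list alone), with a median of -0.47 ± 0.05, a camera adjusted p of 1.2e-06, and adjusted p = 0.18 with an estimated correlation. The neuropeptide gene nlp-12 had -2.13 ± 0.28. The largest change was that of nlp-32, at -2.89 ± 0.21, a peptide gene known from the epidermis rather than from neurons. Without prep 1, 12 genes of the list were higher.

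**Figure D2:**
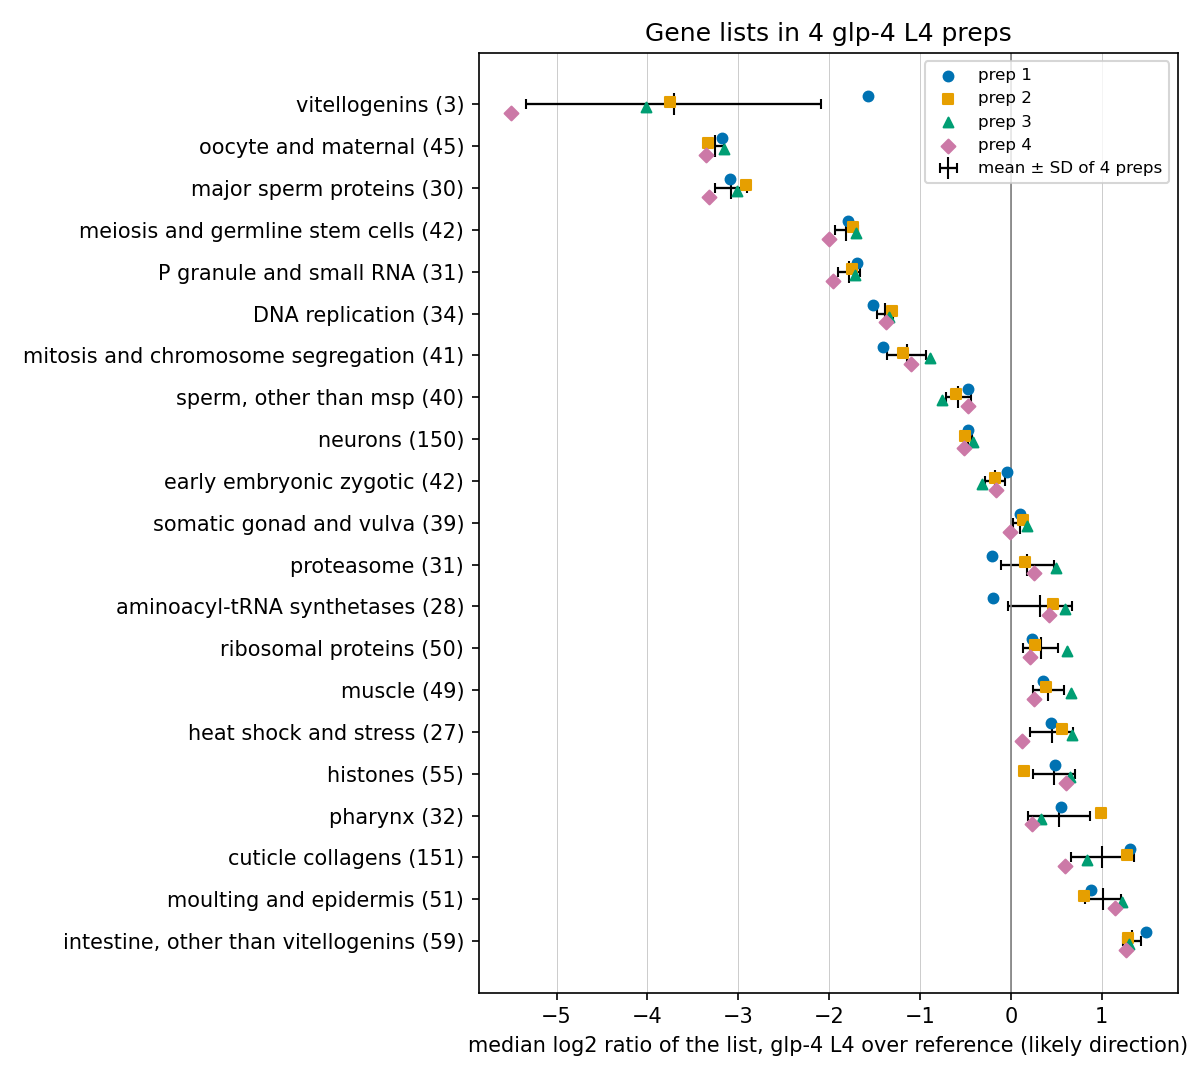
Median log2 ratio of glp-4 L4 over reference (likely direction, x axis) of each gene list (y axis, with the number of genes measured on all 4 arrays) in 4 preps, as coloured points with the mean ± SD in black. Oocyte genes lie at -3.26 and intestinal genes at 1.33 on average, and the vitellogenins have the widest spread.

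Camera made no call for the early embryonic, somatic gonad, heat shock, pharynx, synthetase and proteasome lists. Early embryonic zygotic genes had a median of -0.17 ± 0.11, with 4 of 43 higher and 13 lower (4 and 13 adjusted over the list alone). Among them sdz-6 had 2.75 ± 0.58 and the homeobox gene pal-1 -1.96 ± 0.46. The other higher ones, named after their values were seen, were cwn-1 at 0.71 ± 0.48, sdz-27 at 0.56 ± 0.05 and elt-7 at 0.40 ± 0.09; 1 was higher without prep 2 and 2 without prep 3 or prep 4. Genes of the somatic gonad and vulva had a median of 0.10 ± 0.08, with 13 of 40 higher and 8 lower (14 and 9 adjusted over the list alone), led by pes-8 at 2.93 ± 0.16 and nid-1 (nidogen) at 2.40 ± 0.26, and without prep 4 there were 5 lower. Heat shock and stress genes had a median of 0.45 ± 0.24, with 14 of 27 higher and 8 lower (14 and 9 adjusted over the list alone). Its largest ratios were those of the small heat shock genes sip-1 at -4.80 ± 0.37 and hsp-12.6 at -4.50 ± 0.75, and 5 were lower without prep 2 or prep 4. The camera adjusted p was 0.23, 0.20 and 0.22 in this order.

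The pharynx list had a median of 0.53 ± 0.34, with 16 of 33 higher and 7 lower (17 and 8 adjusted over the list alone), and a camera adjusted p of 0.051 (adjusted p = 0.52 with an estimated correlation). Its higher side was mostly 1 family: of 13 abu genes 12 were higher and 0 lower, with a median of 1.41 ± 0.82, while of the other 20 genes 4 were higher and 7 lower, with a median of -0.29 ± 0.14, a split made after the values were seen. The pharyngeal gland gene phat-4 had 2.87 ± 0.38 and abu-1 2.23 ± 0.67. The list passed without prep 4 (adjusted p = 0.0095) and did not without prep 1, 2 or 3 (0.064, 0.059 and 0.062). It also passed with arrays centred, the title code as a block, preps 3 and 4 averaged or a fit per probe, with adjusted p from 0.031 to 0.048.

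Camera called the ribosomal protein list but not the synthetase and proteasome lists, and leaving out single preps moved the counts of all 3. Of 52 ribosomal protein genes, 18 were higher, 3 lower and 31 did not pass (17 higher and 2 lower adjusted over the list alone), with a median of 0.33 ± 0.19 and a camera adjusted p of 0.0021 (adjusted p = 0.52 with an estimated correlation). The largest were rpl-11.1 at -2.23 ± 0.50 and rpl-37.2 at 0.92 ± 0.24; the other lower ones, named after their values were seen, were rpl-4 at -0.61 ± 0.53 and rpl-39 at -0.43 ± 0.24. The rps and rpl families, taken by name after the values were seen, also hold genes outside this list. Their camera p was adjusted over 144 families of genes that share a name. The small subunit family (rps) had 12 of 24 higher and 0 lower (camera adjusted p = 0.0027, and adjusted p = 0.83 with an estimated correlation). The large subunit family (rpl) had 9 of 35 higher and 4 lower and did not pass (camera adjusted p = 0.17), and the difference between the subunits was not tested. The higher count of the list was 5, 6 and 6 without preps 2, 3 and 4, and 1 was lower without prep 2 or prep 4. Of 29 aminoacyl-tRNA synthetases, the family of glp-4, 9 were higher and 2 lower (9 and 2 adjusted over the list alone), with a median of 0.32 ± 0.36 and a camera adjusted p of 0.053. The list passed with rank-based camera (adjusted p = 0.034). The prolyl- and aspartyl-tRNA synthetase genes pars-1 and dars-1 had 1.09 ± 0.48 and 1.09 ± 0.64, and the 2 lower ones, named after their values were seen, were rars-2 at -0.89 ± 0.35 and lars-1 at -0.59 ± 0.34. Without prep 1, 14 synthetases were higher and the list passed (adjusted p = 0.0031), while without prep 2, 3 or 4 there were 4.

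Of 31 proteasome genes, 1 was higher and 2 lower (0 and 1 adjusted over the list alone), with a median of 0.18 ± 0.29 and a camera adjusted p of 0.22. These were pbs-5 at 0.53 ± 0.23, rpn-6.2 at -0.78 ± 0.18 and, named after its value was seen, rpn-1 at -0.53 ± 0.32. Without prep 1, 9 were higher and the list passed (adjusted p = 0.027), without prep 2, 3 or 4 the higher count was 0, and 1 was lower without prep 2 or prep 4.

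Genes on the X chromosome lay above those on the autosomes. Germline-expressed genes are known to be scarce on X, which is why the chromosomes were compared. The median of 2239 X-linked genes minus that of 12699 autosomal genes was 0.192 ± 0.014 (SD, n = 4; exact two-sided sign-flip permutation p = 0.125, the smallest that 4 preps allow). Of X-linked genes 32.4% were higher, against 21.8% of autosomal genes (odds ratio 1.72, Fisher's exact p = 5.1e-26), and 16.21% were lower, against 25.5% (odds ratio 0.565, Fisher's exact p = 9.7e-23). These p-values are over genes, which are not independent. Without the germline, oocyte, sperm and mitosis lists the difference was 0.179. This left 2235 X-linked and 12474 autosomal genes, so few genes were removed. It cannot show whether the difference would remain without germline genes outside those lists. Of the autosomes, V had a median of 0.06 ± 0.07 and I, II, III and IV had negative medians, the lowest on I at -0.17 ± 0.02.

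**Figure D3:**
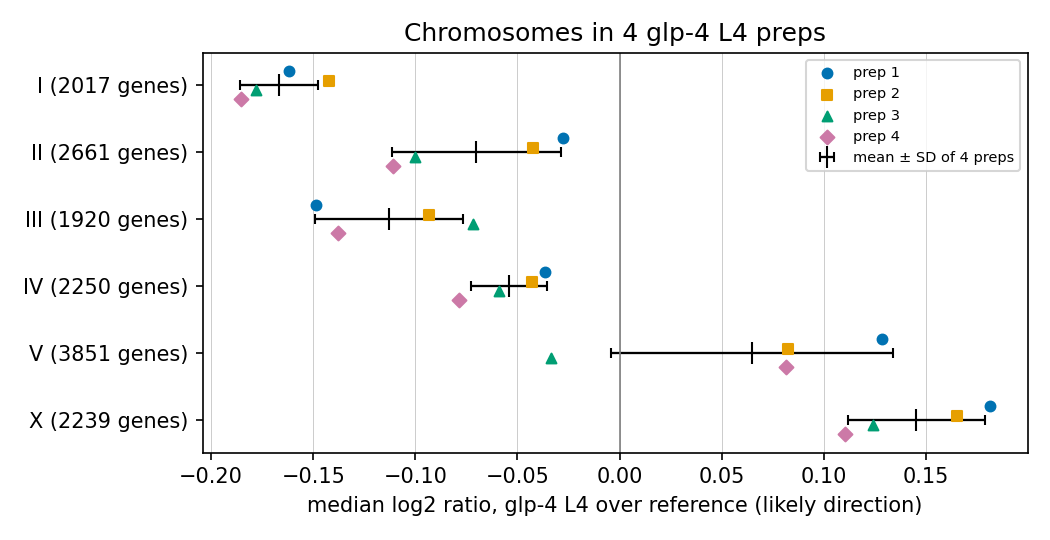
Median log2 ratio of glp-4 L4 over reference (likely direction, x axis) of the genes of each chromosome (y axis, with gene numbers) in 4 preps, as coloured points with the mean ± SD in black. X lies at 0.15 ± 0.03 and chromosome I at -0.17 ± 0.02.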

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

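Of 80 sets of 4 values examined for 1 prep standing apart (by Dixon's ratio), 3 stood out, and chance gives about 4, at 1 in 20. The ribosomal protein median was 0.61 on prep 3, against 0.21 to 0.27 on the other preps. The sperm gene msd-3 had -2.68 on prep 2, against -3.11 to -3.05 on the others. The muscle gene dim-1 had 2.099 on prep 3, against 1.66 to 1.73. No explanation was tested for these 3.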

How the results depend on the processing

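The alternatives were set before the data were examined, and no list median, named gene or X difference changed direction under those run, apart from turning every sign, which swaps the sides by construction. No paired analysis was possible because there is 1 group, and its 4 preps give 16 sign patterns. The 8987 items different from 0 became 5305 without moderation (2524 higher, 2781 lower) and 3980 at an absolute mean log2 ratio of at least 1 (2063 higher, 1917 lower). The 4874 lower items became 3093 at an adjusted p under 0.01. Leaving out a prep gave 6570 to 9983. Past 2-fold, the 876 higher and 842 lower items became 666 and 717 without prep 2, 607 and 703 without prep 3, 621 and 650 without prep 4, and 668 and 708 with preps 3 and 4 averaged, so which side is larger is not stable. Centring turned the higher and lower counts from 4113 and 4874 to 4354 and 4312. With the correlation estimated, a test with 3 degrees of freedom, 15 called lists lost their call. That setting leaves the values as they are, and the medians over genes of the mean ratio (above, medians per prep were averaged instead) are: meiosis -1.76, P granule -1.85, oocyte -3.17, sperm -0.61, major sperm proteins -3.09, vitellogenins -3.77, replication -1.36, mitosis -1.17, histones 0.48, collagens 0.96, moulting 1.01, muscle 0.37, intestine 1.27, neurons -0.48 and ribosomal proteins 0.33; 7 of 21 lists had an unadjusted p under 0.05 and 0 passed. On the same median, the pharynx gained a call at 0.58 centred, 0.58 with the title code as block, 0.64 with preps 3 and 4 averaged, 0.70 per probe and 0.60 without prep 4, and synthetases at 0.28 with rank-based camera and 0.47 without prep 1, as did the proteasome at 0.28 without prep 1. No other left-out prep gave these lists a call, and over all 4 the medians ran from 0.49 to 0.68, 0.19 to 0.47 and 0.052 to 0.28. Their causes were not tested. Of the named genes, vit-5, pars-1, dars-1 and pbs-5 lost their call without moderation, and pbs-5 also with preps 3 and 4 averaged (adjusted p = 0.053) or without prep 2, 3 or 4. Under the alternatives, 55 counts of list members moved by over 1.5 times and 491 did not. The X difference ranged from 0.179 to 0.198. Signal over background was not used here, so its effect on dim spots is open.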

Other observations

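The gene families, the neighbours and the patterns below were chosen after the data were seen, and so were all tests in this part except the adult-onset genes and the spread of neuronal genes. The adult-onset hypothesis itself came from values already seen, and means of some of its genes were known.

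Several gene families had mostly higher or mostly lower members. Among 144 families of at least 10 genes that share a name, 42 passed camera, 0 with an estimated correlation (9 had an unadjusted p under 0.05 there). UDP-glucuronosyltransferases (ugt) had 51 of 62 genes higher and a median log2 ratio of 1.62 ± 0.33 (SD, n = 4), with a camera adjusted p of 9.2e-17 (adjusted p = 0.64 with an estimated correlation). Cytochrome P450 (cyp) genes had 39 of 67 higher and a median of 0.76 ± 0.12, P-glycoproteins (pgp) 12 of 14 and 1.53 ± 0.27, lysozymes (lys) 7 of 10 and 1.88 ± 0.11, and vacuolar ATPase subunits (vha) 14 of 17 and 0.99 ± 0.20. For cyp, pgp and lys adjusted p = 0.64 with an estimated correlation, and for vha 0.74. Glutathione S-transferases (gst) had 14 of 31 higher and 6 lower, with a median of 0.43 ± 0.28 and a camera adjusted p of 0.039 (adjusted p = 0.89 with an estimated correlation). Of the transporter families, slc had 15 of 31 higher and 4 lower (adjusted p = 0.016, and adjusted p = 0.88 with an estimated correlation). The zipt family had 4 higher and 4 lower of 12 (adjusted p = 0.80), which did not pass. Nuclear pore genes (npp) had 15 of 21 lower and a median of -0.72 ± 0.25, and bath genes 17 of 29 lower and -1.003 ± 0.24 (for both, adjusted p = 0.64 with an estimated correlation). No called family changed sign when arrays were centred (0 of 42).

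Near dod-21 and dod-24 in the gene order of WBcel235 lies cld-1, with a mean of 5.14 ± 1.61. Of the 13 measured genes of this locus group, 8 were higher, 2 were lower (C32H11.3 at -1.40 ± 0.20 and C32H11.7 at -0.93 ± 0.21) and 3 did not pass (srz-15 at 0.48 ± 0.63, irg-6 at -0.25 ± 0.86 and C32H11.4 at -0.42 ± 0.76). Over 10654 pairs of neighbouring genes without a shared name prefix, Spearman's rho between their means was 0.158, against at most 0.032 in 1000 shuffles. Of these pairs 55.6% had 1 sign. Genes with only a sequence name never counted as sharing a prefix, so related neighbours whose probes bind each other's transcripts may remain among the pairs. Among unnamed probes the most positive were 2777823 at 6.89 ± 0.92 and 2781873 at 6.74 ± 0.84, and the most negative 2777825 at -4.76 ± 1.55 and 2792633 at -4.62 ± 0.55.

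The vitellogenin median ranged over 3.93 between preps, and prep 1 stood 2.85 above the mean of the others. Compressed ratios on prep 1 would move oocyte genes too. The median of the oocyte and maternal list ranged over 0.193 and lay 0.098 higher on prep 1, which argues against compression for that list as a whole. Fewer adults in some reference RNA would also move oocyte RNA, but embryos in a mixed-stage reference can carry maternal RNA. The median therefore does not decide on fewer adults. Single members moved both ways from prep 1 to prep 4, such as perm-4 from -1.25 to -3.90 and cey-2 from -3.83 to -1.91. Nor does the median exclude compression for single genes. A candidate explanation is that preps differ in time near the adult moult: of 6 adult-onset genes, 5 followed the vitellogenin profile with r over 0.8, against 12.9% of named genes (one-sided exact binomial p = 0.00019, for genes that are not independent). The 6 genes were col-7, col-62, col-119, col-140, ule-1 and ule-4. Values per prep of col-19, ule-3 and ule-5, which share a family name with them, had been seen before. The adult collagen col-19 had 2.15, 1.26, -0.60 and -1.89 on preps 1 to 4. Preps 3 and 4 share a title code, and ule-4 had -0.32 and -0.98 on preps 1 and 2, against -2.91 and -3.15 on preps 3 and 4. For such genes a difference that goes with the code cannot be told apart from age. The gene col-62 fell at each step, with 5.16, 3.98, 3.34 and 2.04. Preps 1, 2 and 3 each have a different code, so only its step from prep 3 to prep 4 lies within a code. The labels give no staging, so age stays a hypothesis.

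Neuropeptide genes (the flp, nlp and insulin-like ins families) were lower than other neuronal genes by -0.48 ± 0.11 in 4 of 4 preps. The 84 had a median of -0.71 ± 0.09 (57 lower) and 57 others -0.22 ± 0.06 (20 lower). This leaves out 9 peptide genes known from the epidermis (nlp-24 to nlp-32, 5 lower), with which the difference was -0.47 ± 0.09. By family, flp had 17 of 21 lower and a median of -0.89 ± 0.09. The nlp family, with the epidermal genes, had 35 of 52 lower, 2 higher and a median of -0.72 ± 0.08. The ins family had 10 of 20 lower and 3 higher, and its median of -0.30 ± 0.04 lay near that of the other neuronal genes. Dilution of neuronal RNA would move both groups alike only if both were made in neurons alone. Neither group was checked for expression outside neurons, so the difference cannot count for or against dilution. Dimmer spots of the other genes may still pull their ratios to 0: their median SD was 0.0041 higher (permutation p = 0.39 one-sided, 0.62 the other way), which leaves this open, and intensities were not used here. No biological explanation was tested.

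The synthetase medians were positive on 3 of 4 preps. The cytosolic synthetases lay 0.0044 ± 0.20 above the mitochondrial ones and higher in 2 of 4 preps, so a response of the cytosolic ones cannot be told apart from none at this spread. The synthetase median minus the mean of the ribosomal and proteasome medians was 0.066 ± 0.20, so no difference from those lists was seen at this spread. That neither shows nor excludes a shift shared with other genes of protein turnover.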
